A study of Mus musculus with 8 samples.

How the data were processed

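RNA was measured in pDC and cDC sorted from spleens of leukemia-bearing mice, in 4 groups of 2 libraries, each library from a pool of 3 to 6 mice per the labels. Per the labels' protocols, RNA was isolated with Trizol and a Direct-zol kit and libraries were made with the NEBNext Single Cell/Low Input kit. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq (2.17.1.14), checked with FastQC (0.11.6), trimmed with cutadapt (2.1), aligned to mm10 with HISAT2 (2.1.0), counted per gene with featureCounts (Subread 2.0.0) and analysed with limma. The labels' extraction text speaks of sorted leukemia cells, while the titles name pDC and cDC. The libraries were taken as DC from the titles, and DC marker genes were checked against them. The deposited table holds whole-number read counts, 1 row per Entrez gene ID and 1 column per library, and a read count is the unit of everything computed here. The strandedness of the counting, the gene annotation behind it and the handling of reads with several alignments are not given in the sources used here. Genes that share reads with a near copy, such as Tgtp1 and Tgtp2 or members of the H2 family, and genes with an antisense partner are therefore uncertain.

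Columns with D5W in their name were taken as vehicle (dextrose in water) and columns with LBH as panobinostat (LBH589), and 0 columns were left without a group. Of the 27179 gene IDs, 25275 (92.99%) matched a symbol in the gene name table, and the 1904 others stayed in the tests without a name. The 15 mitochondrial gene IDs had 0 counts in all libraries, so no mitochondrial share was computed. Total counts were 13124861 to 20657429 per library. No molecular identifiers are recorded, so reads are not independent molecules and floors cover counting error only. Where a group had 0 counts a fold was given as a lower bound with 3 counts over the group as the floor.

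Tests were run in R (4.3.3) with edgeR (4.0.16). Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 14238, and libraries were scaled by TMM. All 8 libraries were fitted together with 1 coefficient per group, which left 4 residual degrees of freedom and 2.3 prior degrees of freedom. Contrasts were tested by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, with adjusted p = 0.05 as the threshold. The 4 contrasts were panobinostat against vehicle in pDC, the same in cDC, the difference between those effects (pDC minus cDC) and pDC against cDC in vehicle. Standard errors of log2 fold changes were derived from the quasi-likelihood statistic. CPM (the depth-scaled count of edgeR's cpm function) used the TMM-scaled library sizes, and log2 CPM used a prior count of 2.

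There were 32 gene lists, covering interferons and their responses, antigen presentation, DC identity and activation, markers of other cell types, drug targets and cellular processes, written before the files were opened. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Unless another source is given, adjusted p values of lists are from camera with the preset correlation. Some genes stand in more than 1 list, such as Ccr2 in the cDC2 and monocyte lists. Genes were named by a rule: in each comparison, among called genes with a mean log2 CPM of at least 3 and no overlap between the groups' libraries, the 8 largest changes per direction; from each list the 4 tested members with the smallest p; and a fixed set of interferon, DC and histone deacetylase genes, with any Ifna gene that had a mean of at least 5 counts in a group. Coordinates are those of mm10 (GRCm38).

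The labels give every group replicates 1 and 2. The deviations of libraries from their group means were correlated between groups over genes: the 12 same-number library pairs gave 6 distinct correlations, from 0.15 to 0.49, all above 0.1, so the numbers were taken to pair the samples. The pairing comes from the replicate numbers of the labels together with this check, and the labels do not say which animals share a number. The analysis as reported carried no block for this pairing. With the replicate number as a block, 0 genes were called in pDC and 0 for the difference.

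The pipeline was tested on simulated data with known changes. With the spread of all 8 libraries (13844 genes), panobinostat effects in pDC were called in 0% of genes changed 1.5-fold or 2-fold, 3.4% of those changed 4-fold and 58.7% of those changed 16-fold. For cDC these shares were 0%, 0%, 9.3% and 28.6%, and for pDC against cDC 0%, 0%, 14.6% and 39.6%, with 0 unchanged genes called. With the spread of the 4 cDC libraries (13834 genes), 23.6% of genes changed 2-fold and 86% of those changed 4-fold were called for cDC, with 6 unchanged genes called. A list of 64 genes shifted by 0.5 log2 units in simulated cDC was tested with camera at the spread of all 8 libraries. It had p = 0.00066 with the preset and 0.0122 with the estimated correlation, and 0 of 100 unchanged lists fell under 0.05. The simulated genes varied independently of each other, so the error of the preset correlation in lists whose genes move together was not tested. In the data the estimated correlation was 0.156 for the type I interferon response list in cDC and 0.973 for ribosomal protein genes in pDC.

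The alternatives tried were RLE, upper quartile and library size scaling; no filter and a stricter one (5 CPM in 2 libraries); the replicate number, or the pool, as a block; each library left out; only the 4 libraries compared; robust empirical Bayes; a minimum fold of 1.5 (glmTreat); DESeq2 (1.42.0) and limma-voom. Added after the data were seen were voom with sample quality weights, offsets for GC content and transcript length, those offsets with the block, each cell type alone with the block, the offsets without panobinostat pDC replicate 2, and an estimated correlation with these fits or with a block. GC content and length came from the longest transcript of each gene in GENCODE M21 and were available for 13702 of the tested genes (96.2%). Tables and figures used Python (3.11.15), pandas (2.3.3), scipy (1.17.1) and matplotlib (3.10.9). No library was left out of the analysis as reported. Groups of 2 libraries were too small for tests of a library against its group or for regrouping the samples. The version that the processing notes give for R was left out.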

Results

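RNA sequencing measured transcripts in splenic dendritic cells (DC) sorted from C57BL/6 mice that carried a leukemia and were treated for 2 days with panobinostat, an inhibitor of histone deacetylases, or with vehicle, a dextrose solution. Plasmacytoid DC (pDC), known for their type I interferon output, and conventional DC (cDC), known for antigen presentation to T cells, were sorted from pools of 3 to 6 mice. Each of the 4 groups (pDC or cDC, panobinostat or vehicle) had 2 libraries, which the labels call biological replicates, for 8 in total. Total counts were 18142443 and 18756193 in vehicle pDC and 19902188 and 13124861 in panobinostat pDC. In cDC they were 19411880 and 20657429 with vehicle and 20429668 and 19484237 with panobinostat. Levels below are means of depth-scaled counts (CPM) ± SD and changes are log2 fold changes ± standard error (SE), with n = 2 libraries per group. Adjusted p values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 14238 genes tested. Floors cover counting error only.

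Panobinostat pDC replicate 2 stood apart from the other 7 libraries. It held 10745 genes with at least 1 count, where panobinostat pDC replicate 1 held 14927 and the other libraries 16109 to 19950. Across genes, which are not independent replicates, the log2 CPM of the panobinostat pDC replicates correlated with r = 0.801. Those of the other groups' replicates correlated with 0.965 in vehicle pDC, 0.97 in vehicle cDC and 0.973 in panobinostat cDC. On the first principal component, with 63.2% of the variance, this library lay at -299, the other pDC libraries between -60.1 and -30.9 and the cDC libraries between 99.8 and 111.2. The cell-type genes matched the labels in every library: the mean log2 CPM of the pDC identity list was 8.29 to 8.53 in the pDC libraries and 3.12 to 3.5 in the cDC libraries.

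**Figure D1:**
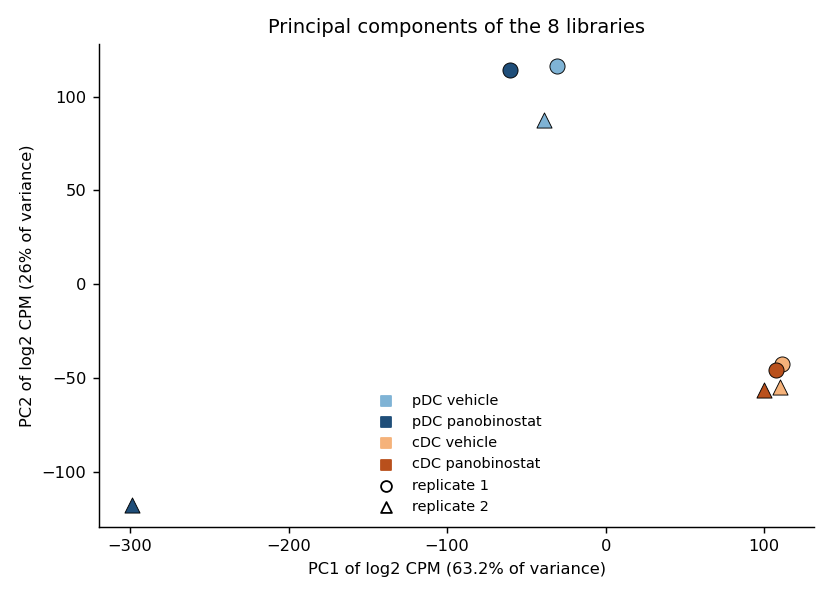
Scores of the 8 libraries on the first and second principal components of log2 CPM (63.2% and 26% of the variance), 1 point per library, coloured by cell type and treatment, with circles for replicate 1 and triangles for replicate 2. Panobinostat pDC replicate 2 lies at -299 on the first component and -117.7 on the second, away from the other pDC libraries.

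The first comparison asked whether panobinostat changed transcripts of pDC, those of the interferon response among them. Of 14238 genes, 13 passed the test, 2 higher and 11 lower, in the fit without a replicate block, and 0 passed with that block. Ifi27, an interferon-induced gene, rose by 2.06 ± 0.18 log2 units, from 44.1 ± 1.31 to 184 ± 21.3 CPM (SD, n = 2; adjusted p = 0.0458). Klri2, which codes for a killer cell lectin-like receptor, rose by 3.61 ± 0.22 log2 units, from 9.94 ± 0.00762 to 121 ± 11.9 CPM (SD, n = 2; adjusted p = 0.0143). Plekho2, which codes for a pleckstrin homology domain protein, fell by 3.54 ± 0.19 log2 units, from 76.5 ± 6.33 to 6.56 ± 0.308 CPM (SD, n = 2; adjusted p = 0.0133). Srebf2, which codes for the main transcription factor of cholesterol synthesis genes, fell by 2.69 ± 0.26 log2 units, from 334 ± 78.4 to 51.5 ± 12.1 CPM (SD, n = 2; adjusted p = 0.0464). Akna, a transcription factor gene with an AT-hook, fell from 134 ± 23.9 to 16.7 ± 1.3 CPM (SD, n = 2; log2 fold change -3.00 ± 0.23, adjusted p = 0.0364).

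Pxn and Sbf1, genes of a focal adhesion adaptor and a myotubularin-related protein, fell with log2 fold changes of -2.67 ± 0.25 and -2.39 ± 0.22. The lysosomal enzyme genes Gaa and Man2b2 fell by 1.88 ± 0.19 and 1.73 ± 0.18 log2 units, and the acyl-protein thioesterase gene Lypla2 by 1.73 ± 0.15 log2 units. Adjusted p values were 0.0458 for Pxn, Sbf1 and Lypla2 and 0.0499 for Gaa and Man2b2. The remaining called genes, Rnf144b, Gatm and Scarb1, lay outside the rule for named genes and were named after their values were seen. Rnf144b had 24 and 22 counts in the vehicle replicates and 0 in both panobinostat replicates, and was at least 12.4-fold lower if 3 counts over the group are set as the floor. Gatm had 18 and 20 counts against 0 and 0, and was at least 10.2-fold lower by the same floor. Scarb1, the gene of a lipoprotein receptor, fell by 1.54 ± 0.15 log2 units (adjusted p = 0.0499). In mm10 coordinates the main genes are Ifi27 (Entrez Gene 52668, chromosome 12, 103434189 to 103440245), Klri2 (320407, chromosome 6, 129729041 to 129740484), Plekho2 (102595, chromosome 9, 65552577 to 65580087), Srebf2 (20788, chromosome 15, 82147269 to 82205379) and Akna (100182, chromosome 4, 63367123 to 63411094).

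The count of 13 called genes rested on the fit. With the replicate number as a block it was 0, and with offsets for GC content and transcript length it was 0, where the 11 lower genes had a median log2 fold change of -1.24 in place of -2.67. It was 719 (101 higher, 618 lower) without panobinostat pDC replicate 2, 8227 without panobinostat pDC replicate 1, and 0 without any one of the other 6 libraries. RLE scaling, the median-of-ratios scaling of DESeq2, left 1 gene higher and 1 lower, a share of 50% higher in place of 15.4%. DESeq2 called 988 genes and limma-voom 0, while 2119 genes had an unadjusted p under 0.05 (804 higher, 1315 lower) where 712 were expected by chance. That number was 1193 and 1382 without vehicle pDC replicates 1 and 2, and 9187 and 3533 without panobinostat pDC replicates 1 and 2. In the 4 pDC libraries alone it was 541 of 12680, with 0 called. In 2241 genes (15.7%) both panobinostat libraries lay above both vehicle libraries and in 3773 genes (26.5%) below them, against 16.7% per direction by chance. The median log2 fold change of all genes was -0.141, and -0.285 when scaled by library size only. Over the 24 alternative fits the direction of Ifi27 (at least 1.63), Klri2 (3.33 to 3.99) and Plekho2 (-3.72 to -2.35) did not change. They were called in 8, 11 and 11 of these fits.

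**Figure D2:**
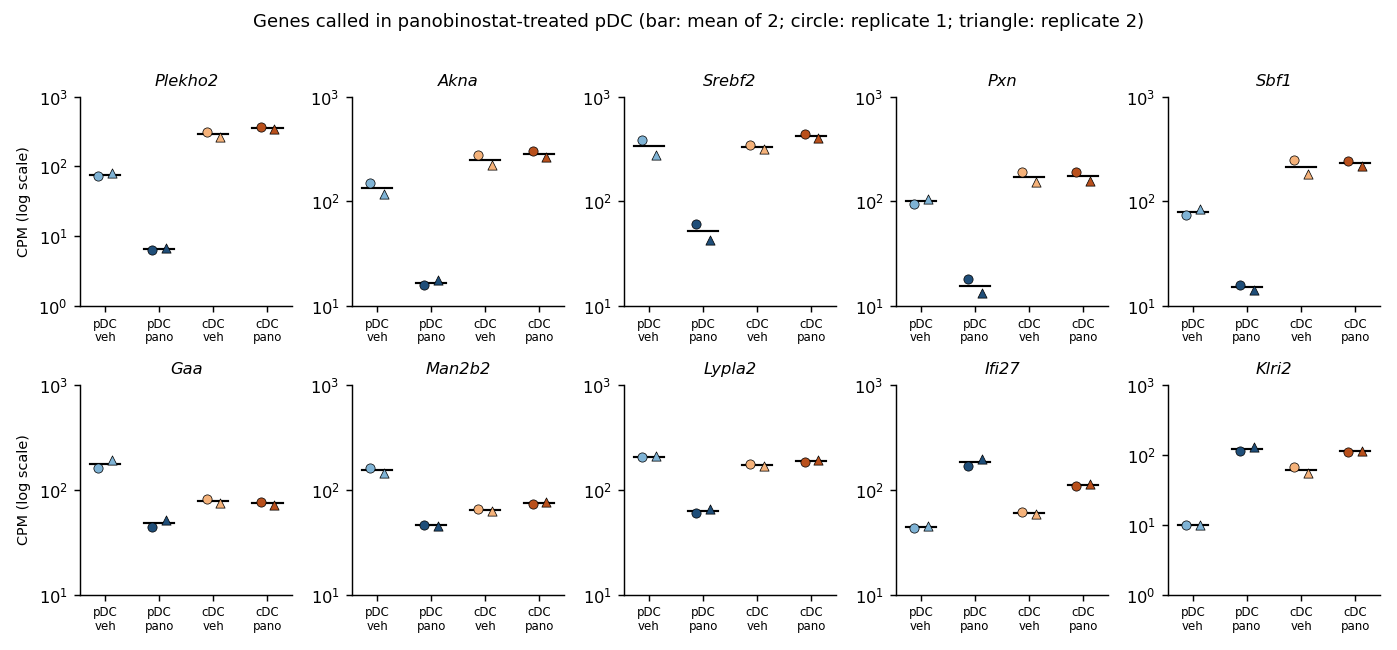
CPM, on log axes, of 10 genes called in panobinostat pDC, in the 4 groups, with circles for replicate 1, triangles for replicate 2 and bars for the mean of 2. In pDC, Plekho2 lies at 76.5 CPM on average in vehicle and 6.56 CPM in panobinostat, and Klri2 at 9.94 and 121 CPM.

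The type I interferon response list, the genes that interferon alpha and beta induce, rose as a set in pDC by camera. This test sets a list against the other genes with a preset correlation (64 genes, median log2 fold change 0.38, 44 above 0, adjusted p = 4.76e-06). It did not pass with an estimated correlation (adjusted p = 0.782; range over its alternatives 1.58e-07 to 0.96). The median was 0.25 without vehicle pDC replicate 1 and 0.63 without vehicle pDC replicate 2, and the call with the preset correlation held in both fits. Of its members, Ifi27 was called over all genes, and 2 higher and 2 lower were called when adjusted over the list alone. These were Ifi27 and Ms4a4c higher and Pml and Dtx3l lower, and over all genes Ms4a4c, Pml and Dtx3l did not pass. Ms4a4c was 41.2 ± 17.3 CPM in vehicle and 309 ± 151 in panobinostat, Pml 390 ± 19 and 138 ± 2.11, and Dtx3l 131 ± 1.81 and 39.4 ± 10.1 (SD, n = 2). Ifit1, which passed neither way, was 12.5 ± 5.04 and 70.3 ± 49.7 CPM (SD, n = 2). Irf7, the transcription factor gene that drives interferon alpha expression, stood at 1100 ± 385 CPM in vehicle and 844 ± 275 in panobinostat, and Isg15, an interferon-induced ubiquitin-like modifier, at 40.8 ± 18.1 and 46.7 ± 5.07 (SD, n = 2). The interferon gamma response list also passed camera (26 genes, median 0.58, mean 0.15, adjusted p = 0.0303), but not with an estimated correlation (adjusted p = 0.782). Its call was lost without vehicle pDC replicate 1 (median 0.32, adjusted p = 0.114) and without panobinostat pDC replicate 1 (median 0.08, adjusted p = 0.277), with a range of adjusted p over all alternatives of 0.0013 to 0.96.

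Transcripts of type I interferons themselves were at or near 0. The 14 Ifna genes in the table held 8 counts over all 8 libraries, at most 1 per gene and library. Ifnb1 had 2 and 2 counts in vehicle pDC, 20 and 0 in panobinostat pDC, and 0 in all 4 cDC libraries, and was too low to test. Ifnk, of the same family, was the only interferon gene tested and had a log2 fold change of -1.66 ± 1.32 in pDC (adjusted p = 0.579).

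**Figure D3:**
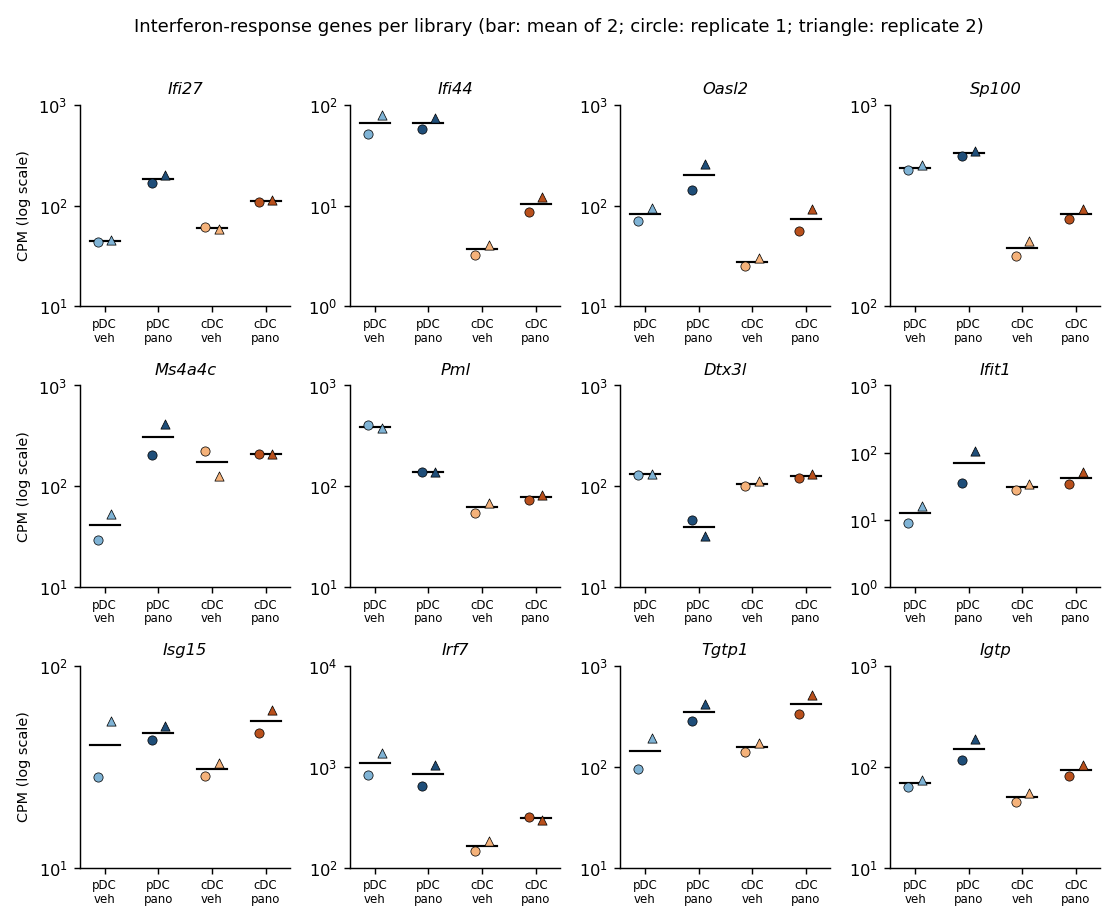
CPM of named interferon response genes on log axes, in the 4 groups, with circles for replicate 1, triangles for replicate 2 and bars for the mean of 2. Ifi27 lies at 44.1 and 184 CPM on average in vehicle and panobinostat pDC and at 60 and 111 CPM in vehicle and panobinostat cDC.

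Oxidative phosphorylation genes, nuclear genes of the respiratory chain, were higher as a set in panobinostat pDC (median log2 fold change 0.63, 41 of 44 above 0, adjusted p = 9.26e-09). Ribosomal protein genes were too (median 0.59, 49 of 50 above 0, adjusted p = 2.66e-08). With an estimated correlation the adjusted p values were 0.782 and 0.787, and ranges over the alternatives were 1.23e-12 to 0.96 and 6.99e-18 to 0.96. Both calls rested on panobinostat pDC replicate 2: without it the medians were 0.10 (adjusted p = 0.199) and -0.16 (adjusted p = 0.92). They were 0.37 and 0.28 without vehicle pDC replicate 1 and 0.96 and 1.01 without panobinostat pDC replicate 1, and that of ribosomal protein genes was 0.94 without vehicle pDC replicate 2. For example, Ndufb3, a complex I subunit gene, was 44.2 ± 12.9 CPM in vehicle and 108 ± 50.8 in panobinostat, and Rpl23, a large ribosomal subunit gene, 272 ± 88.5 and 539 ± 294 (SD, n = 2). No member of either list passed the test over all genes.

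MHC class II processing genes passed camera as a set in pDC (median 0.58, 11 of 15 above 0, adjusted p = 0.000896, and 0.782 with an estimated correlation). Over all genes 0 members were called, and 2 higher and 1 lower when adjusted over the list alone. H2-Ob, which codes for a chain of H2-O, was 39.7 ± 12.9 CPM in vehicle and 254 ± 53.9 in panobinostat, and Ciita, the class II transactivator gene, 264 ± 5.05 and 78.2 ± 46.3 (SD, n = 2). The call of the class II list was lost without vehicle pDC replicate 1 (median 0.31, adjusted p = 0.0849) and without panobinostat pDC replicate 2 (median 0.09, adjusted p = 0.522), over a range of 6.84e-06 to 0.96. Without panobinostat pDC replicate 1 its median was 0.90. Immediate early genes, which tissue dissociation induces, had a median of 0.58 (15 of 25 above 0, adjusted p = 0.0186, and 0.782 with an estimated correlation). Their call was lost without vehicle pDC replicate 1 (median 0.37, adjusted p = 0.108) and without panobinostat pDC replicate 1, where the median changed sign (-0.25, higher by camera's direction, adjusted p = 0.34), over a range of 2.21e-05 to 0.96. It was lost as well with the stricter filter (median 0.43, adjusted p = 0.0558) and in the pDC libraries alone with the block (median 0.06, adjusted p = 0.098).

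Markers of other cell types were measured in the same pDC libraries. B cell markers were higher as a set (median 0.69, 13 of 16 above 0, adjusted p = 0.0471, and 0.876 with an estimated correlation). Cd79a, a B cell receptor subunit gene, was 13 ± 10.1 CPM in vehicle and 42 ± 25.4 in panobinostat (SD, n = 2). The B cell call was lost without vehicle pDC replicate 1 (median 0.51, adjusted p = 0.26), without panobinostat pDC replicate 1 (median 1.10, adjusted p = 0.142) and without replicate 2 (median 0.13, adjusted p = 0.52), over a range of 0.001 to 0.977. Upper quartile scaling (median 0.73, adjusted p = 0.058) and GC and length offsets (median 0.77, adjusted p = 0.216) ended it too, and without vehicle pDC replicate 2 the median was 1.18. NK cell markers had a median of 1.07 (adjusted p = 0.0698). They passed with the replicate block (median 1.55, adjusted p = 0.0434, and 0.622 with an estimated correlation), without panobinostat pDC replicate 2 (median 1.06, adjusted p = 0.0442) and without vehicle pDC replicate 2 (median 1.13, adjusted p = 0.0266), over a range of 7.96e-06 to 0.96. Other fits that called the NK list were the stricter filter (median 2.71, adjusted p = 0.0148), library size scaling (1.02, 0.0166), the 4 pDC libraries alone (1.31, 0.00224) and those with the block (0.85, 7.96e-06, and 0.808 with an estimated correlation). Klrk1 and Klrd1, genes of NK cell receptors, stood at 32.9 ± 14 and 193 ± 52.4 CPM in vehicle and at 333 ± 219 and 620 ± 300 CPM in panobinostat pDC (SD, n = 2). The pDC identity list had a median of 0.17 (adjusted p = 0.122), which passed with the block (median 0.17, adjusted p = 0.019, and 0.622 with an estimated correlation; range 0.00525 to 0.96) and with the offsets (median 0.55, adjusted p = 0.0267, and 0.938 with an estimated correlation). Its members Siglech, a pDC surface lectin gene, and Tcf4, the lineage's transcription factor gene, were 4150 ± 126 and 1240 ± 246 CPM in vehicle and 5990 ± 787 and 1330 ± 390 in panobinostat (SD, n = 2).

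Histone deacetylase genes, among them the targets of the drug, had a median log2 fold change of -0.61 in pDC (18 of 25 below 0, adjusted p = 0.347). Hdac1 and Hdac5 had log2 fold changes of -0.05 ± 0.14 and -1.71 ± 0.27 (adjusted p = 0.126 for Hdac5), and Cdkn1a, a gene that such inhibitors often induce, 0.67 ± 0.56 (adjusted p = 0.592). Cholesterol synthesis genes had a median of 0.17 (adjusted p = 0.141), with Srebf2 the only member called. They passed with GC and length offsets (median 0.69, adjusted p = 0.00393), with the block added to these (0.66, 0.0013) and with the offsets but without panobinostat pDC replicate 2 (0.35, 0.0318). With an estimated correlation these fits gave 0.938, 0.775 and 0.96, and the range over the alternatives was 0.0013 to 0.96. Toll-like receptor 7 and 9 signalling (median -0.36), DC activation (-0.29), MHC class I processing (0.15) and the unfolded protein response (-0.02, higher by camera's direction) did not pass in pDC. The class I list passed with the offsets (median 0.56, adjusted p = 0.0101) and with the block added to these (0.52, 0.000795), with 0.938 and 0.819 at an estimated correlation and a range of 0.000795 to 0.977. DC activation passed with the offsets but without panobinostat pDC replicate 2 (-0.60, 0.0318, and 0.96 with an estimated correlation; range 0.0318 to 0.994). Other lists that did not pass were apoptosis (median 0.14), response to histone deacetylase inhibitors (0.03, mean 0), inflammatory cytokines (0.24, mean -0.04) and cDC1 and cDC2 identity (0.03, mean -0.16, and 0.40). Inflammatory cytokines passed in the 4 pDC libraries alone (median 1.59, adjusted p = 9.47e-05) and there with the block (adjusted p = 0.000546, and 0.808 with an estimated correlation), over a range of 9.47e-05 to 0.96. The median and the test differed in sign for p53 targets (median -0.17), pan-cDC identity (median 0.03, mean -0.38) and neuronal genes (median 0.16, or 0.02 with members at 0 counts set to their bound, mean -0.76). They also differed for T cell markers (median 0.03, mean -0.66) and myeloid progenitor genes (median 0.09, mean -0.48). Monocyte, neutrophil and plasma cell markers had medians of -0.32 (-0.2 with bounds), 0.53 and 0.43 (mean -0.47) and did not pass, except monocyte markers with the block and the offsets together (-0.98, 0.027, and 0.775 with an estimated correlation; range 0.027 to 0.977).

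Calls adjusted over the list alone among the lists that did not pass in pDC were 1 higher and 5 lower for pan-cDC identity, 3 and 4 for cDC2 identity, 3 and 2 for inflammatory cytokines, and 2 and 0 for NK cell markers. There were 2 lower for pDC identity and for T cell markers, 1 lower for DC activation and for histone deacetylase genes, 2 higher for cDC1 identity and 1 higher for monocyte markers. Some lists that did not pass in pDC did so without 1 library. Cell cycle genes had a median of -0.06 (higher by camera's direction), which became 0.61 without vehicle pDC replicate 1 (adjusted p = 0.00049) and 0.35 without panobinostat pDC replicate 2 (adjusted p = 0.0126). Erythroid and platelet markers had a median of 0.56, which became 1.47 without panobinostat pDC replicate 2 (adjusted p = 0.00699). Over all alternatives the highest adjusted p was 0.995 for cell cycle genes and 0.989 for erythroid and platelet markers.

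The second comparison asked the same of cDC, the antigen-presenting population. Of 14238 genes, 0 passed edgeR's test (smallest adjusted p = 1), with 206 at an unadjusted p under 0.05 (111 higher, 95 lower), fewer than the 712 expected by chance. That number was 966 of 14868 genes without panobinostat pDC replicate 1, 950 of 15049 without panobinostat pDC replicate 2 and 1324 of 13556 in the 4 cDC libraries alone. It was 113 and 116 without vehicle cDC replicates 1 and 2, and 108 and 70 without panobinostat cDC replicates 1 and 2. The common dispersion was 0.358 over all 8 libraries, 0.0621 in the 4 of cDC alone and 0.723 in the 4 of pDC. The spread shared in edgeR's fit was thus wider than in cDC and narrower than in pDC. Its 0 calls do not show that cDC did not respond, and pDC p values can be too small. DESeq2 called 14 genes, limma-voom 0 and limma-voom with sample quality weights 16. A fit of the 4 cDC libraries alone with the replicate block, added later, called 106 (57 higher, 49 lower). Both panobinostat libraries lay above both vehicle libraries in 3166 genes (22.2%) and below them in 2682 (18.8%), against 16.7% per direction by chance. Genes named below were thus not called and are given as values.

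Type I interferon response genes were higher as a set in panobinostat cDC (median log2 fold change 0.47, mean 0.54, 61 of 64 above 0, adjusted p = 3.44e-27 by camera). With an estimated correlation the adjusted p was 0.181, and 0.0286 when the replicate block was added to it; the range over the alternatives was 1.05e-30 to 0.576. In 49 of the 64 genes both panobinostat libraries lay above both vehicle libraries, and no left-out library ended the call. Ifi27 was 60 ± 2.36 CPM in vehicle and 111 ± 4.09 in panobinostat (SD, n = 2; log2 fold change 0.88 ± 0.17). Irf7 was 165 ± 24.5 and 309 ± 13.8 CPM, Oasl2, an oligoadenylate synthetase-like gene, 27.6 ± 3.69 and 73.9 ± 25.4, and Ifi44, another interferon-induced gene, 3.66 ± 0.566 and 10.4 ± 2.61 (SD, n = 2). Interferon gamma response genes were also higher as a set (median 0.65, 23 of 26 above 0, adjusted p = 7.66e-15, and 0.181 with an estimated correlation), with a median of 0.39 without panobinostat cDC replicate 2. Their GTPase members Tgtp1 and Tgtp2, whose near-identical sequences leave the split of reads uncertain, had log2 fold changes of 1.44 ± 0.41 and 1.39 ± 0.42, and Igtp was 50.1 ± 7.48 and 93 ± 15.9 CPM (SD, n = 2).

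Cholesterol synthesis genes were higher in all 23 members in panobinostat cDC (median 0.48, adjusted p = 1.33e-13, and 0.181 with an estimated correlation), with a median of 0.29 without panobinostat cDC replicate 2. Fdps and Sqle, enzyme genes of that pathway, were 90.6 ± 14.3 and 57.7 ± 7.56 CPM in vehicle and 181 ± 28 and 101 ± 22.6 in panobinostat (SD, n = 2). Unfolded protein response genes had a median of 0.37 (21 of 24 above 0, adjusted p = 3.17e-09, and 0.2 with an estimated correlation). Hspa5, the endoplasmic reticulum chaperone gene, was 1520 ± 257 and 2650 ± 447 CPM (SD, n = 2). Immediate early genes had a median of 0.58 (21 of 25 above 0, adjusted p = 5.08e-09, and 0.2 with an estimated correlation). Egr1, a transcription factor gene of that list, was 360 ± 141 and 1050 ± 21 CPM (SD, n = 2). MHC class II processing genes had a median of 0.41 (12 of 15 above 0, adjusted p = 3.08e-05, and 0.516 with an estimated correlation). H2-Ob was 224 ± 25.8 and 417 ± 6.27 CPM (SD, n = 2).

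MHC class I processing genes had a median of 0.25 in cDC (19 of 21 above 0, adjusted p = 2.81e-08, and 0.435 with an estimated correlation). Tap2, a peptide transporter gene, had a log2 fold change of 0.57 ± 0.21. Their call was lost without panobinostat cDC replicate 2 (median 0.05, adjusted p = 0.0656), with a range over the alternatives of 7.07e-15 to 0.696. The median was 0.12 without vehicle cDC replicate 1, and 0.46 without vehicle cDC replicate 2 as well as without panobinostat cDC replicate 1. The cDC1 identity list had a median of 0.48 (adjusted p = 3.79e-05, and 0.2 with an estimated correlation). It lost the call without vehicle cDC replicate 1 (median 0.24, adjusted p = 0.12) and without panobinostat cDC replicate 2 (median 0.26, adjusted p = 0.0585), over a range of 3.56e-13 to 0.655, and its median was 0.76 without vehicle cDC replicate 2. Ribosomal protein genes had a median of 0.20 (48 of 50 above 0, adjusted p = 0.000101, and 0.768 with an estimated correlation). They lost the call without vehicle cDC replicate 1 (median 0.11, adjusted p = 0.12) and without panobinostat cDC replicate 2 (median 0.06, adjusted p = 0.28), over a range of 4.59e-09 to 0.926. Their median was 0.34 without vehicle cDC replicate 2 as well as without panobinostat cDC replicate 1. Toll-like receptor 7 and 9 signalling genes had a median of 0.12 (13 of 22 above 0, adjusted p = 0.0313, and 0.2 with an estimated correlation) and lost the call in 10 of the alternative fits (range over all alternatives 0.0066 to 0.696). Those 10 included the fits without panobinostat pDC replicate 1 (median 0.12, adjusted p = 0.147), panobinostat pDC replicate 2 (0.10, 0.168), vehicle cDC replicate 1 (0.13, 0.165) or panobinostat cDC replicate 2 (0.05, 0.245). Library size scaling turned the sign of that list's median (-0.02, higher by camera's direction, adjusted p = 0.0906), which was 0.07 without vehicle cDC replicate 2.

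Markers of other cell types differed between the cDC groups. B cell markers were lower as a set in panobinostat cDC (median -1.22, 13 of 16 below 0, adjusted p = 1.87e-10, and 0.313 with an estimated correlation). Their call was lost without vehicle cDC replicate 2 (median -0.02, adjusted p = 0.11; range 3.49e-22 to 0.696), and the median was -0.76 without panobinostat cDC replicate 1 and -1.95 without replicate 2. Ighm, the immunoglobulin heavy chain mu gene, was 1270 ± 487 CPM in vehicle and 536 ± 85.8 in panobinostat (SD, n = 2). Plasma cell markers were lower as a set (median -2.09, 9 of 10 below 0, adjusted p = 1.75e-08, and 0.181 with an estimated correlation), with a median of -0.89 without vehicle cDC replicate 2. Ighg2c, an immunoglobulin heavy chain gene, was 50.4 ± 27 and 5.84 ± 0.962 CPM (SD, n = 2). NK cell markers were higher in all 14 members (median 2.38, adjusted p = 1.02e-08, and 0.313 with an estimated correlation), but both panobinostat libraries lay above both vehicle libraries in only 3 of them. The mean log2 CPM of the NK list was -0.02 and 2.62 in vehicle cDC and 1.39 and 4.89 in panobinostat cDC. The NK call was lost and the median changed sign without panobinostat cDC replicate 2 (-0.68, higher by camera's direction, adjusted p = 0.701; range 2.57e-26 to 0.701), and the median was 5.03 without vehicle cDC replicate 2. Klra8 and Xcl1, an NK receptor gene and a chemokine gene of NK and T cells, had log2 fold changes of 3.25 ± 2.23 and 3.02 ± 1.65.

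Ccr2, the chemokine receptor gene of monocytes, had the only call when adjusted over the list alone in cDC, 1 higher in each of the cDC2 and monocyte lists. It stood at 50.9 ± 5.84 CPM in vehicle and 167 ± 34.4 in panobinostat (SD, n = 2; log2 fold change 1.71 ± 0.21). No member of any list passed over all genes. Lists that did not pass in cDC were oxidative phosphorylation (median 0.03), apoptosis (0.03, mean -0.04), response to histone deacetylase inhibitors (0.13, mean -0.06), histone deacetylase genes (-0.05), p53 targets (-0.01), neuronal genes (0.09) and monocyte markers (-0.35, mean -0.02, higher by camera's direction). Hdac1 and Cdkn1a had log2 fold changes of 0.01 ± 0.14 and -0.01 ± 0.56 in cDC. Ifnk had a log2 fold change of 0.37 in cDC.

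For the remaining lists of cDC, the call depended on a left-out library or on the block, and values in parentheses are the median and the adjusted p without that library or with the block. T cell markers had a median of 0.68 (adjusted p = 0.243). They passed with the block (0.70, 0.0249, and 0.264 with an estimated correlation), without panobinostat cDC replicate 1 (1.05, 7.78e-07), without vehicle cDC replicate 2 (1.71, 0.00955) and, with the direction turned, without panobinostat cDC replicate 2 (-0.91, 0.0086), over a range of 7.78e-07 to 0.926. Pan-cDC identity had a median of 0.26 (adjusted p = 0.0751), and passed with the block (0.28, 0.045, and 0.449 with an estimated correlation) and without panobinostat cDC replicate 1 (0.30, 0.0213), over a range of 0.00893 to 0.877. The cDC2 identity list had a median of 0.01 (adjusted p = 0.0751), and passed without panobinostat cDC replicate 2 (0.21, 0.00172), vehicle cDC replicate 1 (0.21, 0.00407), panobinostat pDC replicate 1 (0.02, 0.0312) or panobinostat pDC replicate 2 (0.00, 0.0314). DC activation genes had a median of -0.28 (adjusted p = 0.08) and passed without panobinostat cDC replicate 2 (-0.43, 0.00357). Cd86, Cd40 and Ccr7, genes of costimulation and migration in that list, had log2 fold changes of 0.28, -0.09 and -0.45 in cDC. Cell cycle genes had a median of -0.19 and passed without vehicle cDC replicate 2 (-0.31, 0.0415). Erythroid and platelet markers had a median of -0.15, which was -1.73 without panobinostat cDC replicate 1 (9.03e-07), -0.75 without vehicle cDC replicate 2 (0.0117) and 0.50 without panobinostat cDC replicate 2 (0.00246). Neutrophil markers (median -0.90) passed without panobinostat cDC replicate 2 (-0.76, 0.00831), as did the pDC identity list (-0.07, 0.0173, from a median of -0.07). Inflammatory cytokines (median 0.26, mean -0.02) passed without panobinostat cDC replicate 1 (0.32, 0.0313), as did myeloid progenitor genes (0.36, 0.0313, from a median of 0.41).

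Some of these lists also passed in fits of fewer libraries or genes, with the median and adjusted p in parentheses. In the 4 cDC libraries alone these were DC activation (-0.31, 0.0163), cell cycle (-0.22, 0.000102), inflammatory cytokines (0.32, 0.0231), pan-cDC identity (0.23, 0.037) and cDC2 identity (-0.01, 0.0496, higher by camera's direction). With the block in those 4 libraries they were DC activation (-0.31, 0.0209), cell cycle (-0.21, 0.00202), inflammatory cytokines (0.35, 0.000691), pan-cDC identity (0.26, 0.00893), T cell markers (0.48, 0.0217) and erythroid and platelet markers (-0.42, 0.0191). None of these 6 held with an estimated correlation in that fit (adjusted p 0.576 to 0.688). With the stricter filter they were DC activation (-0.29, 0.0184), cell cycle (-0.21, 0.0393) and inflammatory cytokines (0.55, 0.00811). Over all alternatives the adjusted p ranged from 0.00357 to 0.877 for DC activation, 0.000102 to 0.926 for cell cycle, 0.000691 to 0.942 for inflammatory cytokines and 0.00172 to 0.948 for cDC2 identity. It ranged from 9.03e-07 to 0.927 for erythroid and platelet markers, 0.00831 to 0.721 for neutrophil markers, 0.0173 to 0.988 for pDC identity and 0.0313 to 0.926 for myeloid progenitor genes.

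**Figure D4:**
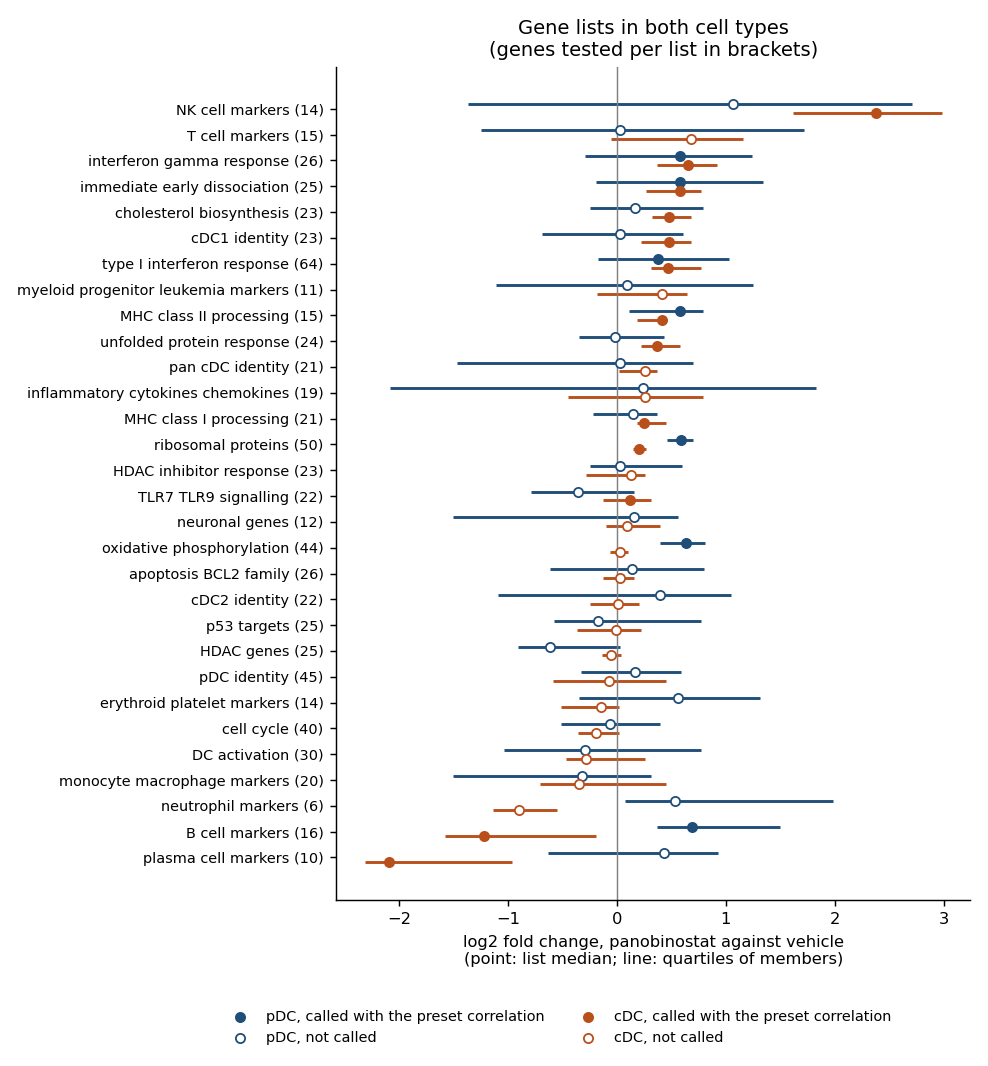
Median log2 fold changes of the gene lists in pDC and in cDC, panobinostat against vehicle, with 1 point per list and cell type, filled where camera with the preset correlation called the list, and lines for the quartiles of its genes. The type I interferon response list lies at 0.38 in pDC and 0.47 in cDC; library size scaling turns the toll-like receptor list in cDC from 0.12 to -0.02.

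The third comparison asked whether the effect of panobinostat differed between pDC and cDC, by a test of the interaction. Plekho2 was the only gene of 14238 called, with an interaction of -3.83 ± 0.25 log2 units (adjusted p = 0.0455). In cDC it was 288 ± 37.5 CPM in vehicle and 351 ± 14.9 in panobinostat (SD, n = 2). The Plekho2 call was lost with the replicate block, which left 0 genes, and held in 7 of 23 alternative fits, with log2 fold changes from -3.99 to -2.60 and adjusted p from 2.04e-24 to 0.999. Srebf2, which stood at 332 ± 21.1 CPM in vehicle cDC and 425 ± 25.5 in panobinostat cDC (SD, n = 2), did not pass for the difference. Ifi27 had an interaction of 1.18 ± 0.24 (adjusted p = 0.359), Pml of -1.84 ± 0.25 (adjusted p = 0.214) and Ms4a4c of 2.63 ± 0.67 (adjusted p = 0.405). In all, 1107 genes had an unadjusted p under 0.05 for the difference (254 higher, 853 lower) where 712 were expected by chance, and the median of all genes was -0.134. That number was 7843 and 2664 without panobinostat pDC replicates 1 and 2, 604 and 578 without vehicle cDC replicates 1 and 2, and 566 and 594 without panobinostat cDC replicates 1 and 2. The count of 1 became 279 without panobinostat pDC replicate 2, 6457 without panobinostat pDC replicate 1 and 0 without any one of the other libraries. DESeq2 called 303 genes and limma-voom 0.

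For gene lists, B cell markers had a higher log2 fold change in pDC than in cDC (median of the interaction 1.51, 13 of 16 above 0, adjusted p = 4.24e-06, and 0.871 with an estimated correlation, range 5.82e-12 to 0.959). The median was 2.60 without vehicle pDC replicate 2, 0.92 without vehicle cDC replicate 2 and 2.74 without panobinostat cDC replicate 2. Oxidative phosphorylation genes did as well (median 0.52, 40 of 44 above 0, adjusted p = 4.37e-07, and 0.871 with an estimated correlation, range 4.56e-10 to 0.959), but not without panobinostat pDC replicate 2 (median 0.04, adjusted p = 0.306). Their median was 0.32 and 0.85 without vehicle pDC replicates 1 and 2 and 0.91 without panobinostat pDC replicate 1. Ribosomal protein genes had a median of 0.33 (47 of 50 above 0, adjusted p = 0.00039, and 0.871 with an estimated correlation, range 1.59e-09 to 0.975). It was 0.08 without vehicle pDC replicate 1 (adjusted p = 0.233), -0.33 without panobinostat pDC replicate 2 (adjusted p = 0.306, and -0.36 with adjusted p = 0.00269 when the offsets were added) and 0.02 with GC and length offsets (adjusted p = 0.84). It was 0.72 without vehicle pDC replicate 2, 0.78 without panobinostat pDC replicate 1 and 0.18 without panobinostat cDC replicate 1. Plasma cell markers had a median of 2.09 (8 of 10 above 0, adjusted p = 0.0267, and 0.871 with an estimated correlation, range 0.0012 to 0.959). This was lost, with the median and adjusted p in parentheses, without vehicle pDC replicate 1 (1.62, 0.33), panobinostat pDC replicate 1 (-2.50, 0.398, higher by camera's direction), vehicle cDC replicate 2 (1.30, 0.0832) or panobinostat cDC replicate 1 (1.93, 0.0591). The call also ended with the pool as a block (1.33, 0.118), GC and length offsets (2.00, 0.0876) and the stricter filter (2.13, 0.0934). Type I interferon response genes did not differ between the cell types by this test (median -0.14, mean -0.18, higher by camera's direction, adjusted p = 0.655, with 2 lower when adjusted over the list alone). Interferon gamma response genes did not either (median -0.25, adjusted p = 0.655), nor did NK cell markers (median -1.85, higher by camera's direction, adjusted p = 0.746). As edgeR called 0 genes in cDC, an overlap of called genes between the cell types could not be tested.

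Without 1 library, 8 further lists passed for the difference. Medians and adjusted p values are given in that order. Without panobinostat pDC replicate 2 these were cell cycle (median 0.73, adjusted p = 0.00186), erythroid and platelet markers (1.86, 0.00186), MHC class I processing (-0.49, 0.0377), toll-like receptor 7 and 9 signalling (-0.42, 0.0377) and pan-cDC identity (-0.50, 0.0377). Without vehicle pDC replicate 1 they were cell cycle (0.96, 5.8e-05), erythroid and platelet markers (1.85, 0.043) and pan-cDC identity (-0.63, 0.0426). Erythroid and platelet markers (3.12, 0.000957) and T cell markers (-1.01, 0.0172) passed without panobinostat cDC replicate 1, MHC class II processing (0.49, 0.00306) without vehicle pDC replicate 2, and pDC identity (0.19, 0.00851) without panobinostat cDC replicate 2. With the block and the offsets together, monocyte markers (-0.54, 0.0307) and pDC identity (0.65, 0.0228) passed, with 0.91 for each at an estimated correlation. The highest adjusted p of each list in this paragraph over its alternatives was 0.959 to 0.984.

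The last comparison set pDC against cDC in vehicle and asked whether the sorted populations carried the transcripts of their labels. Of 14238 genes, 1385 passed, 714 higher and 671 lower in pDC. Siglech was 4150 ± 126 CPM in pDC and 2.42 ± 1.2 in cDC (SD, n = 2; log2 fold change 10.74 ± 0.51, adjusted p = 0.000659). Tcf4 was 1240 ± 246 and 52.8 ± 4.12 CPM (SD, n = 2; 4.55 ± 0.30, adjusted p = 0.00135). Cox6a2, a cytochrome c oxidase subunit gene, was 503 ± 9.46 and 0.302 ± 0.166 CPM (SD, n = 2; 10.67 ± 0.46, adjusted p = 0.000659). Bst2, a surface antigen gene of mouse pDC, was higher in pDC by 5.11 ± 0.43 log2 units (adjusted p = 0.00217). Zbtb46, the transcription factor gene of cDC, was 5.32 ± 4.17 CPM in pDC and 145 ± 12 in cDC (SD, n = 2; -4.77 ± 0.89, adjusted p = 0.0254). H2-M2, a nonclassical MHC class I gene, was lower in pDC with a log2 fold change of -8.88 ± 0.76 (adjusted p = 0.00383). Flt3, the receptor gene of the DC growth factor, did not differ (log2 fold change -0.30, adjusted p = 0.344).

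The pDC identity list was higher in vehicle pDC, with 38 of 45 genes called and 40 when adjusted over the list alone. Its median was 4.55 (adjusted p = 3.03e-59, and 0.0173 with an estimated correlation). Pan-cDC identity was lower, with 12 of 21 genes called and 17 when adjusted over the list alone. The list's median was -3.15 (adjusted p = 1.69e-16, and 0.0394 with an estimated correlation, 0.0608 with the block added). The cDC1 list was lower, with 15 of 23 genes called lower and 1 higher, and 19 and 1 when adjusted over the list alone. It had a median of -4.95 (adjusted p = 3.53e-13, and 0.054 with an estimated correlation). DC activation genes were lower, with 16 of 30 called lower and 1 higher, and 21 and 1 when adjusted over the list alone. Here the median was -4.17 (adjusted p = 5.22e-13, and 0.0394 with an estimated correlation, 0.054 with the block added). In that list Ccr7 was 901 ± 23.8 CPM in cDC with a log2 fold change of -5.27 ± 0.44 (adjusted p = 0.00199) and Cd86 had a log2 fold change of -4.29 ± 0.74 (adjusted p = 0.0196). Inflammatory cytokine genes were lower, with 7 of 19 called and 13 when adjusted over the list alone. They had a median of -5.74, or -3.08 with members at 0 counts set to their bound (adjusted p = 2.38e-08, and 0.0394 with an estimated correlation, 0.0861 with the block added). The median was -3.42 and -3.46 without panobinostat pDC replicates 1 and 2, -3.54 without vehicle cDC replicate 1 and -3.41 without panobinostat cDC replicate 1. Il12b, which codes for the shared subunit of interleukins 12 and 23, had a log2 fold change of -7.77 ± 0.71 (adjusted p = 0.00269). The cDC2 list had a median of -0.72 and did not pass, and did so without panobinostat pDC replicate 1 (-0.71, adjusted p = 0.00213) or replicate 2 (-0.74, adjusted p = 0.0024) and in the 4 vehicle libraries alone (-0.75, adjusted p = 0.018), over a range of 0.00213 to 0.634.

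Cell cycle genes were lower in vehicle pDC, with 17 of 40 called, and 21 lower and 1 higher when adjusted over the list alone. Their median was -2.60 (adjusted p = 3.42e-12, and 0.336 with an estimated correlation). Rrm2, a ribonucleotide reductase gene, was among them (-3.32 ± 0.49, adjusted p = 0.012). Cholesterol synthesis genes were higher, with 10 of 23 called and 16 when adjusted over the list alone (median 1.27, adjusted p = 2.38e-08, and 0.155 with an estimated correlation). Sqle was among the called (1.74 ± 0.27, adjusted p = 0.0144). MHC class II processing genes were lower, with 4 of 15 called and 5 when adjusted over the list alone (median -0.74, adjusted p = 0.00067, and 0.542 with an estimated correlation), with medians of -0.39 and -1.22 without vehicle pDC replicates 1 and 2. Immediate early genes were lower, with 2 of 25 called and 3 when adjusted over the list alone (median -1.01, adjusted p = 0.00559, and 0.542 with an estimated correlation), with medians of -1.71 without vehicle pDC replicate 2 and -0.55 without vehicle cDC replicate 2. Apoptosis genes were lower, with 5 of 26 called, and 8 lower and 1 higher when adjusted over the list alone (median -1, adjusted p = 0.00952, and 0.15 with an estimated correlation). Unfolded protein response genes were higher, with 2 of 24 called and 1 when adjusted over the list alone (median 0.51, adjusted p = 0.0207, and 0.542 with an estimated correlation). That call was lost, with the median and adjusted p in parentheses here and below, without vehicle pDC replicate 2 (0.39, 0.103), panobinostat pDC replicate 1 (0.52, 0.101) or panobinostat pDC replicate 2 (0.49, 0.102), with the stricter filter (0.47, 0.0552) and in the 4 vehicle libraries alone (0.48, 0.0996), over a range of 0.00289 to 0.674. Neutrophil markers were lower, with 1 of 6 called and 4 when adjusted over the list alone (median -4.01, adjusted p = 0.0253, and 0.202 with an estimated correlation). This was lost without panobinostat pDC replicate 1 (-4.53, 0.0652) or replicate 2 (-4.56, 0.0671), over a range of 0.00105 to 0.391. Toll-like receptor 7 and 9 signalling genes were higher, with 6 of 22 called, and 7 higher and 1 lower when adjusted over the list alone (median 0.10, adjusted p = 0.0426, and 0.202 with an estimated correlation). Tlr7, the sensor of single-stranded RNA, was 311 ± 31.5 CPM in pDC and 27.3 ± 11.8 in cDC (SD, n = 2). That call was lost without panobinostat pDC replicate 1 (0.11, 0.27) or replicate 2 (0.08, 0.266), with the offsets (0.05, 0.0752), with the stricter filter (0.05, 0.109) and in the 4 vehicle libraries alone (0.07, 0.281). The sign of the median turned with RLE scaling (-0.03, 0.0544) and without vehicle cDC replicate 2 (-0.01, 0.0379), both higher by camera's direction, over a range of 0.00465 to 0.674. The median was 0.04 and 0.18 without vehicle pDC replicates 1 and 2 and 0.31 without vehicle cDC replicate 1.

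Type I interferon response genes did not pass as a set between vehicle pDC and vehicle cDC (median 0.20, mean -0.12, adjusted p = 0.298). Of its members 10 were called higher and 4 lower over all genes, and 18 and 14 when adjusted over the list alone. Irf7 was higher in pDC by 2.74 ± 0.35 log2 units (adjusted p = 0.00744) and Pml by 2.67 ± 0.19 (adjusted p = 0.00142). Interferon gamma response genes (median -0.38) had 3 members called in each direction, and 3 higher and 7 lower when adjusted over the list alone. MHC class I processing (median 0.43, adjusted p = 0.0631) passed with the block, with a median of 0.45 and an adjusted p of 0.00677, given below in parentheses in that order. It also passed without vehicle pDC replicate 1 (0.49, 0.0112), vehicle cDC replicate 2 (0.70, 0.00706), panobinostat cDC replicate 1 (0.43, 0.0313) or replicate 2 (0.43, 0.0322) and with library size scaling (0.38, 0.0293), over a range of 0.00677 to 0.918. Monocyte markers (median -3.68, adjusted p = 0.0525) passed with the block (-4.14, 0.0187) and without vehicle pDC replicate 1 (-3.66, 0.0413), panobinostat pDC replicate 1 (-3.65, 0.00129) or replicate 2 (-3.69, 0.00123). They also passed without vehicle cDC replicate 1 (-3.60, 0.0318) or replicate 2 (-3.38, 0.014), and panobinostat cDC replicate 1 (-3.66, 0.0217) or replicate 2 (-3.66, 0.0204), over a range of 6.68e-05 to 0.542. Oxidative phosphorylation (median 0.25, adjusted p = 0.113) passed with the block (0.24, 0.0377) and without vehicle pDC replicate 1 (0.48, 0.00202) or vehicle cDC replicate 2 (0.33, 0.0429), over a range of 0.00202 to 0.899. B cell markers (median -1.34) passed with the block (-1.15, 0.0473) and without vehicle cDC replicate 1 (-2.08, 0.00612), over a range of 0.00612 to 0.94. NK cell markers (median -3.02) did too with the block (-2.67, 0.0421) and without that library (-3.91, 0.00621), over a range of 0.00621 to 0.918. These 5 lists also passed with the pool as a block (adjusted p 0.00969 to 0.0472). With an estimated correlation none of the 5 passed with the replicate block (0.394 to 0.746) or the pool as a block (0.399 to 0.757). Monocyte markers passed as well with the offsets (-3.62, 0.0128, and 0.459 with an estimated correlation) and in the 4 vehicle libraries alone (-3.71, 6.68e-05), and T cell markers with the stricter filter (-0.75, 0.045, higher by camera's direction; range 0.045 to 0.918). Plasma cell markers (median -2.90) passed without vehicle cDC replicate 1 (-3.21, 0.0318) or vehicle pDC replicate 2 (-3.81, 0.0491). Ribosomal protein genes (median 0.05) passed without vehicle pDC replicate 1 (0.33, 0.0376) and, with the direction turned, without vehicle pDC replicate 2 (-0.35, 0.0476). Their ranges were 0.0318 to 0.674 and 0.0376 to 0.99. T cell markers (median -1, mean 0.07), myeloid progenitor genes (0.56), erythroid and platelet markers (0.57), histone deacetylase genes (0.07), response to histone deacetylase inhibitors (-0.63), p53 targets (-0.11) and neuronal genes (-0.29, or -0.21 with bounds) did not pass in the analysis as reported.

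The count of 1385 genes moved with left-out libraries: it was 316 and 349 without vehicle pDC replicates 1 and 2, 288 and 292 without vehicle cDC replicates 1 and 2. It was 555 and 548 without panobinostat cDC replicates 1 and 2, 5531 without panobinostat pDC replicate 1 and 5439 without replicate 2. The median log2 fold change of all genes was 0.022, and -0.107 with RLE scaling.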

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

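The tests of GC content and length, of carried-over RNA in Rnf144b and Gatm, and of carried-over RNA in the 9 other genes were chosen after the result was seen. So were the fits with those offsets, with voom quality weights and of 1 cell type with the block, and the estimated correlation with a block. The design, the gene lists and the other alternatives were fixed before the data were examined.

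Plekho2 and 4 gene lists drew attention because the effect of panobinostat differed between pDC and cDC by the interaction test. The interaction was -3.83 log2 units for Plekho2, and as a median over the list 1.51 for B cell markers, 2.09 for plasma cell markers, 0.33 for ribosomal protein genes and 0.52 for oxidative phosphorylation genes. With an estimated correlation none of the 4 lists passed (adjusted p = 0.871 for each). With the replicate block edgeR called 0 genes for the difference (1252 at an unadjusted p under 0.05), so the Plekho2 call was lost; without it DESeq2 called 303 genes and limma-voom 0. The Plekho2 call was lost when any one of the 6 libraries other than the panobinostat pDC replicates was left out, with 0 genes called for the difference. Ribosomal protein genes had -0.33 without panobinostat pDC replicate 2 and 0.08 without vehicle pDC replicate 1, and 0.02 with the offsets, and oxidative phosphorylation genes 0.04 without panobinostat pDC replicate 2. Plasma cell markers lost the call without vehicle pDC replicate 1 (1.62), panobinostat pDC replicate 1 (-2.50), vehicle cDC replicate 2 (1.30) or panobinostat cDC replicate 1 (1.93), and with the pool as a block (1.33), the offsets for GC content and length (2.00) and the stricter filter (2.13). The call of the B cell list with the preset correlation held without each of the 8 libraries (median 0.92 to 2.74), and the B cell and plasma cell values carry the lower level of these markers in panobinostat cDC.

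The first pattern was that panobinostat pDC replicate 2 stood apart, with oxidative phosphorylation and ribosomal protein genes high. Its depth is not the reason, because the other 3 pDC libraries thinned to the same total still had at least 14672 genes with a count, where this library had 10745. A trend towards short transcripts reaches most of both shifts, by 10000 random lists matched on length and expression. The ribosomal protein list lay at percentile 95.16, within the matched range of 0.77 to 1.08. The oxidative phosphorylation list, with a median of 1.01, lay at 98.66, just above its range of 0.50 to 0.98. Its genes move together (estimated correlation 0.698), while the random lists hold unrelated genes. The matched range is then too narrow, and this test cannot exclude the trend as the whole cause of either shift. Few RNA molecules entering the library is a candidate explanation, since 15.7% of genes at 8 to 32 CPM in the other pDC libraries had no count in it, and at most 0.0557% in any of those libraries. Damaged RNA and a biological difference between the pools stay open, as untested.

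The second pattern was that 11 genes were lower in panobinostat pDC. Their median GC content was 57.7% against 49.6% for all tested genes. With offsets for GC content and length in all 8 libraries no call was left (adjusted p 0.247 to 0.553). In the 9 genes other than Rnf144b and Gatm each fold shrank and each spread grew, with the median log2 fold change going from -2.39 (median SE 0.19) to -1.20 (median SE 0.34). Without panobinostat pDC replicate 2 the median of these 9 was -1.55 with the offsets and -2.37 without offsets, but there 1 library stands for panobinostat pDC. For the 9 genes an effect of the drug and these trends cannot be told apart, because the folds shrank with the offsets but stayed below 0. The loss of the calls does not point to the trends, since the replicate block and limma-voom, without offsets, also left 0 genes. For Rnf144b and Gatm (GC content 48% and 43.2%) the offsets left the median at -7.38, with folds of -7.48 and -7.29 from -7.51 and -7.24, so the fold did not follow the trends. This cannot decide the cause, because with 0 counts in both panobinostat libraries each fold is known only as a lower bound. Loss of cDC RNA carried over into the vehicle pDC libraries is excluded for 9 of the genes, whose smallest fall was 24.3% of the vehicle cDC level where the most that the cDC identity genes allow is 0.489%. For Rnf144b and Gatm the falls were 1.4% and 0.737% of the vehicle cDC level, above that 0.489%, which goes against lost carry-over as the whole cause. Of the other genes with at least 50 CPM in vehicle cDC, 22 stood at under 0.5% of that level in vehicle pDC. Their median log2 fold change was -3.63 (quartiles -5.37 to 0.32), and that of the 46 genes at 0.5% to 1.5% was 1.13 (-1.43 to 2.81). The fall of the 22 genes is no evidence of carry-over, since panobinostat pDC replicate 2 lost many low genes. It had no count in 42.9% of genes at 2 to 8 CPM in the other pDC libraries. An effect of the drug and lost carry-over cannot be told apart for Rnf144b and Gatm. Both lay near the floor (1.2 and 0.995 CPM in vehicle pDC), where that library can lose a gene without either. A response of pDC to panobinostat stays open, as untested.

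The third pattern was that the type I interferon response list was higher in panobinostat cDC, with B cell and plasma cell markers lower and NK cell markers higher. GC content and length trends are excluded as the whole cause, since the median with the offsets was 0.44, from 0.47. With the NK marker level of each library as a covariate the median was 0.38 (quartiles 0.20 to 0.61, 56 of 64 genes above 0). With the B cell marker level it was 0.65 (quartiles 0.38 to 0.98, 62 of 64 above 0). The NK list itself went from 2.38 to 0.09 and the B cell list from -1.22 to -0.20, but each covariate is the mean of that list. Both marker levels were higher in replicate 2 than in replicate 1 of each cDC group. The covariates can therefore hardly be told apart from the replicate number. These fits cannot exclude more NK cells or fewer B cells in the panobinostat pools as the whole cause. Another mixture of cells that these markers do not track, a difference between pools and a response of cDC to panobinostat stay open, as untested, and the list's adjusted p with an estimated correlation was 0.208 with the NK covariate and 0.116 with the B cell covariate.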

How the results depend on the processing

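Chosen after the result was seen were the fits with voom quality weights, with GC and length offsets (alone, with the replicate block, or without panobinostat pDC replicate 2) and of 1 cell type with the block, and the estimated correlation with a block. Values for lists are medians of log2 fold changes. Where no cause is named, the cause was not tested.

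Of 12704 values of named genes under the alternatives, 148 changed sign, all of them called in neither fit. Of 2962 values of lists, 2253 kept sign and side of the threshold, 305 changed sign (285 called in neither fit, 20 called in at least 1), and without such a turn 107 passed only in the alternative and 297 only in the analysis as reported. Of 115 list calls that an alternative added, 44 had a value with an estimated correlation, and 0 of these passed (0.264 to 0.96). In pDC 13 genes were called. The number was 0 with the replicate block, the offsets, both together, the 4 libraries compared, the pDC libraries alone with the block, limma-voom or quality weights, 2 with RLE, 5 with upper quartile, 3 with robust empirical Bayes and with glmTreat, 68 without a filter, 988 with DESeq2, 574 without panobinostat pDC replicate 2 with the offsets, and 0 to 8227 with 1 library left out. In cDC, from 0, it was 14 with DESeq2, 16 with quality weights and 106 in the cDC libraries alone with the replicate block. For the difference, from 1, it was 0 with RLE, library size, the replicate block, the pool block, robust empirical Bayes, glmTreat, limma-voom, quality weights, the offsets or offsets with the block, 5 without a filter, 303 with DESeq2, 27 without panobinostat pDC replicate 2 with the offsets, and 0 to 6457 with 1 library left out. For pDC against cDC, from 1385, it was 627 with the pool block, 4491 with the 4 libraries compared, 3091 with DESeq2, 5228 with quality weights, 6226 without panobinostat pDC replicate 2 with the offsets, and 288 to 5531 with 1 library left out. A lone library left in a group was assumed to vary like the other groups. The common dispersion was 0.358 with all 8 libraries and 0.0804 without panobinostat pDC replicate 2, where 719 genes were called in pDC.

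The type I interferon response list kept its direction in both cell types. In pDC it did not pass with an estimated correlation (0.384), fry (0.384), or an estimated correlation with the replicate block (0.408), the offsets (0.672), both (0.638), the pDC libraries alone with the block (0.352) or the offsets without panobinostat pDC replicate 2 (0.331). In cDC it did not pass with an estimated correlation (0.466), fry (0.466), or an estimated correlation with the offsets (0.437), the offsets and the replicate block (0.436), the cDC libraries alone with the block (0.466) or the offsets without panobinostat pDC replicate 2 (0.441).

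Where at least 1 of the fits called the list, medians changed sign in pDC for cell cycle genes without vehicle pDC replicate 1 (0.614) and without panobinostat pDC replicate 2 (0.352, and 0.42 with offsets), with a lowest value of -1.531 with 1 library left out. They turned for ribosomal protein genes without panobinostat pDC replicate 2 (-0.155, up to 1.013 with another library left out, and -0.171 with offsets) and immediate early genes without panobinostat pDC replicate 1 (-0.254, up to 0.573). In cDC they turned for toll-like receptor signalling with library size scaling (-0.024), and for cDC2 identity without panobinostat pDC replicate 2 (-0.002) and with the 4 libraries compared (-0.007), over -0.098 to 0.21 with 1 library left out. Without panobinostat cDC replicate 2 they turned for T cell (-0.905, up to 1.713), NK cell (-0.678, up to 5.026) and erythroid markers (0.503, over -1.733 to 0.564). For the difference they turned for plasma cell markers without panobinostat pDC replicate 1 (-2.501, up to 2.931) and ribosomal protein genes without panobinostat pDC replicate 2 (-0.327, up to 0.783, and -0.363 with offsets). For pDC against cDC they turned for toll-like receptor signalling with RLE (-0.027) and without vehicle cDC replicate 2 (-0.01, up to 0.309), and ribosomal protein genes without vehicle pDC replicate 2 (-0.353, up to 0.326). The replicate block in all 8 libraries changed no list call beyond those in the results. Among named genes it ended the calls in pDC and for the difference, and for pDC against cDC it ended 2 and added 6. At these depths 14 Ifna genes held 8 counts in all, and whether depth or absent expression explains this was not tested.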

Other observations

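The fit of the 4 cDC libraries alone with the replicate block was chosen after the result was seen; no hypothesis beyond those weighed above was tested.

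That fit had 1 residual degree of freedom and called 106 genes. Among them were the interferon-induced genes Tgtp1 (log2 fold change 1.39), Oasl2 (1.36), Zbp1 (1.18) and Igtp (0.87), the cholesterol synthesis gene Fdps (0.98) and the chaperone gene Hspa5 (0.78). It also called genes of cytotoxic lymphocytes, Gzma (3.06), Ncr1 (2.65), Klra8 (3.14) and Xcl1 (3.13), and the matrix metalloproteinase genes Mmp9 (2.21) and Mmp12 (2.09). All of these were named after their values were seen unless the results above name them.

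Within same-number pairs of libraries, the type I interferon response list had medians of 0.59 and 0.31 in pDC and 0.45 and 0.55 in cDC. Panobinostat cDC replicate 1, whose NK marker level (mean log2 CPM 1.39) was below that of vehicle cDC replicate 2 (2.62), had a median of 0.32 over that library for the same list, with 54 of 64 genes above 0. Panobinostat cDC replicate 2, whose B cell marker level (4.27) was above that of vehicle cDC replicate 1 (3.71), had a median of 0.71, with 60 of 64 genes above 0.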
